A study of Homo sapiens with 3 samples.

How the data were processed

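RNA sequencing was analysed for 3 libraries of OCI-Ly10 cells treated with MZ1 for 6 h. OCI-Ly10 is an established human cell line of diffuse large B cell lymphoma of the activated B cell-like (ABC) subtype. MZ1 is a bifunctional degrader that joins a ligand of the BET bromodomain proteins to a ligand of the von Hippel-Lindau (VHL) ubiquitin ligase. Per the labels, RNA was extracted with Trizol and 1 µg of total RNA went into an Illumina TruSeq RNA kit; whether the libraries kept strand information is not given in the sources used here. The design text names 4 lymphoma cell lines and the treatment protocol also names 14 days, but the labelled samples form 1 group. Untreated cells, other lines and the later time were not analysed here, so levels and their spread are reported and no effect of MZ1. The labels do not say whether the replicates came from separate cultures, and p-values therefore measure only the spread between these samples, which may be technical.

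The deposited count table holds raw read counts for 15808 genes under versioned Ensembl IDs. Per the submitters' processing notes, STAR, edgeR and the hg38 build were used, while versions, the counting tool and its strand setting and the annotation release are not given in the sources used here. Of the genes in the table, 15257 had a count in at least 1 of the 3 libraries, so the table was not filtered on these libraries alone. The deposited log2 table holds log2 CPM computed by the authors for the same genes. Checked against the counts, each value is the log2 of the count over a library constant plus an offset of 0.452 CPM. The constants were 0.663, 0.751 and 0.801 times the column totals of replicates 1, 2 and 3, so the deposited log2 values lie above those from column totals.

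Counts were scaled with TMM factors (0.914, 1.10 and 0.991 for replicates 1, 2 and 3; edgeR 4.0.16, R 4.3.3) and given as CPM, the count relative to the effective library size. Log2 values are log2(CPM + 0.5), which understates differences among low genes. Symbols, positions, gene types and merged exon lengths came from GENCODE release 29 on GRCh38, matched on the ID without its version, for 15668 IDs. The 140 IDs without a match held 0.0315% to 0.0972% of the counts of a library and stayed in the totals. GC content is that of the longest transcript. Exon overlap on opposite strands was found with pyranges 0.1.4. CPM are not corrected for gene length, so a comparison of 2 genes is also one of their lengths, and ratios per kb of merged exons are given for some pairs.

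Column totals were 5474462, 1441246 and 1314812 counts in replicates 1, 2 and 3, where 1 count is worth 0.20, 0.629 and 0.767 CPM. A gene with no count allows up to 0.60, 1.89 and 2.30 CPM (3 counts per library). Intervals of shares are exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

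Genes were tested for differences between libraries with a chi-square test of the 3 counts against equal expression (Poisson, TMM effective libraries), for genes with a mean count of at least 10, with Benjamini-Hochberg adjustment at 0.05. The test compares libraries, not conditions. The biological coefficient of variation was the square root of the common dispersion of edgeR, with an intercept only, after its filter on low counts. A gene counted as expressed at 1 CPM or more in all 3 libraries. For 30 gene lists the median over members was computed per library and placed among 10000 random lists of the same size, drawn from genes with a mean of at least 1 CPM. These percentiles describe the libraries and are not p-values. The ABC list was set against the germinal centre B cell-like list, and 10 gene pairs were compared, as log2 ratios within each library with an exact two-sided sign-flip permutation test. With 3 libraries its smallest p is 0.25, so it could not pass 0.05.

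The lists, pairs, tests and most alternatives were fixed before the data were examined. The genes named are all members of the BET and VHL ligase lists, the 3 highest and the lowest member of each other list by mean CPM, both genes of each pair, the 10 genes with the highest mean CPM and the 10 with the largest SD of log2 values among genes of at least 10 CPM. Some genes and pairs under this rule are not reported here. Other genes are said to have been chosen after their values were seen. Of the 138 genes under this rule, 52 have exons that overlap exons on the opposite strand, and without a known strand setting their reads cannot be told from those of the partner. Members of multigene families (ribosomal protein, histone and HSPA1 genes) can share reads with near-identical copies and are uncertain in the same way.

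Alternatives were size factors of DESeq2 1.42.0, scaling by column totals, the deposited log2 values, other pseudocounts, filters and thresholds, CPM per kb, means in place of medians, another background for random lists and leaving out each replicate. Thinning to equal depth, leaving out genes with opposite-strand exon overlap and removing a GC trend (medians of 20 bins) were added after seeing the data. The chi-square test was tested on simulated data drawn from the real means and library sizes. With no gene changed it called 0 of 10033 genes. Of 200 genes changed in replicate 1, it recovered 35.5% at 1.5-fold, 70.5% at 2-fold and 99.5% at 4-fold. Simulated coefficients of variation of 0.2 and 0.6 were estimated at 19.6% and 54.6%.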

Results

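Gene expression was measured by RNA sequencing in OCI-Ly10 lymphoma cells treated with MZ1 for 6 h, in 3 replicate libraries. The series set out to profile lymphoma lines after MZ1. With 1 labelled group, the data describe expression levels in the treated cells and their spread between libraries, and no change caused by MZ1 was estimated. Replicate 1 held 5474462 counts, replicate 2 held 1441246 and replicate 3 held 1314812. At least 1 CPM (read count relative to the scaled library size) was measured in all 3 libraries for 10743 of the 15808 genes in the table.

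The most abundant transcripts were mitochondrial and translational. MT-RNR2, the large mitochondrial ribosomal RNA, had 38715 ± 10036 CPM (SD, n = 3), and the means that follow are given in the same way. MT-ND4 had 19493 ± 375 CPM, MT-CO1 13765 ± 4574, MT-ATP6 12276 ± 3401, MT-CO2 10519.8 ± 1577, MT-CYB 8892 ± 1052 and MT-ND5 8726 ± 2017 CPM. The highest nuclear genes were TPT1 at 12639 ± 5280.4, RPL13A at 10172 ± 3520.5 and RPS14 at 8464 ± 4862 CPM. These 10 genes together took 13.1%, 15.1% and 15% of the counts in replicates 1, 2 and 3 (exact 95% interval 13.0 to 13.1% in replicate 1 and 15 to 15.1% in replicate 3). The mitochondrial chromosome took 14.9%, 14.2% and 13.7%. The share of ribosomal protein genes was less even, at 16.2%, 8.81% and 14.0%.

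Replicates 2 and 3 resembled each other more closely than either resembled replicate 1. Across 13174 genes, which are not independent replicates, Pearson's r of log2(CPM + 0.5) was 0.899 between replicates 2 and 3, 0.846 between replicates 1 and 3 and 0.827 between replicates 1 and 2. By the chi-square test, 6728 of 10016 genes varied among the 3 libraries beyond counting noise at an adjusted threshold of 0.05, and 2854 of 8447 did without replicate 1. Among genes with a mean count of at least 50, 4631 of 5707 varied among the 3 libraries. Tallies of varying genes within lists are to be read against these shares. In pairs, 5890 of 10488 genes differed between replicates 1 and 2 and 4700 of 10388 between replicates 1 and 3. Between replicates 2 and 3 the tally was 2858 of 8447, the same comparison as that without replicate 1 but with library sizes scaled over all 3 libraries. Replicate 1 was the deepest, which gives pairs with it more power, so these tallies do not rank the pairs by spread alone. With libraries thinned to equal depth, 5204 of 8294 genes varied among the 3 libraries. No pair agreed within counting noise, and the counts do not tell separate cultures from repeated libraries of 1 culture. The biological coefficient of variation was 39.4%, and 30.1% without replicate 1.

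The 10 genes with the largest spread between libraries each overlap the exons of an abundant gene on the opposite strand. Of the 15668 genes in the table with a GENCODE match, 6706 overlap exons of an opposite-strand gene of any level. AL138963.3 (ENSG00000273149.1, chromosome 13, 45340039 to 45341183, plus strand), which overlaps the translation-associated gene TPT1, had 32.4, 9656 and 9963 CPM in replicates 1, 2 and 3. AC011603.2, which overlaps the tubulin gene TUBA1B, had 2.20, 1068 and 929.7 CPM. BEST1, an ion channel gene opposite the ferritin gene FTH1, had 1.0, 104 and 309.9 CPM, and GPS2, a corepressor subunit gene opposite the translation factor gene EIF5A, had 1.60, 195 and 399 CPM. The others were AC068888.1 at 3.0, 422 and 609.9 CPM (opposite EIF4B), AL354733.3 at 0.20, 106 and 124 CPM (opposite HNRNPK), AC034102.4 at 0.400, 126 and 109.7 CPM (opposite PA2G4) and AC025423.4 at 0.20, 98.7 and 78.2 CPM (opposite MDM2). AC097460.1, opposite H2AFZ, had 0, 35 and 128 counts, and AL133230.1, opposite PTPN1, had 0, 46 and 103 counts. Of the partners, TUBA1B had 1439 ± 314 and HNRNPK 1089 ± 151 CPM. Other partners moved more, and in both directions. TPT1 had 6643, 16597 and 14677 CPM in replicates 1, 2 and 3. H2AFZ, chosen after its values were seen, had 776, 169 and 234 CPM. As a class, antisense genes took 0.251%, 2.04% and 2.09% of the counts, with exact 95% intervals of 0.247 to 0.255% in replicate 1, 2.01 to 2.06% in replicate 2 and 2.07 to 2.12% in replicate 3.

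Differences between libraries also followed the GC content of the genes. Spearman's rho was computed across the 7494 genes of at least 10 CPM with a known GC content, which are not independent replicates. For GC content with the log2 difference it was -0.435 for replicate 2 minus 1, -0.139 for replicate 3 minus 1 and 0.466 for replicate 3 minus 2. In the most GC-rich of 8 equal bins (median 61.0% GC) the median log2 difference was -1.37 for replicate 2 minus 1 and -0.24 for replicate 3 minus 1.

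**Figure D1:**
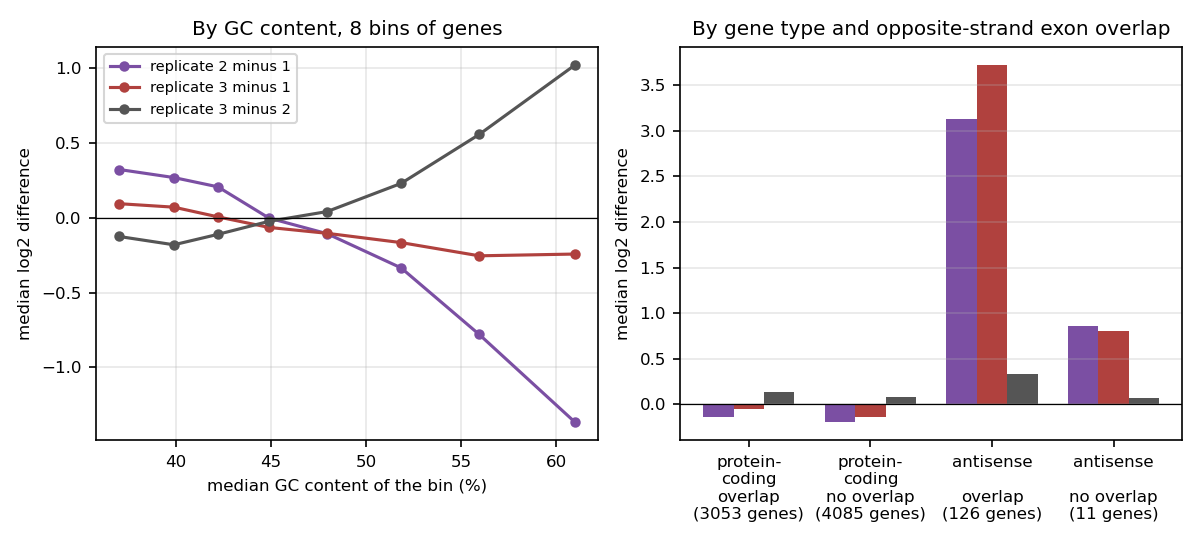
Median log2 differences between pairs of libraries (y axes), on the left over 8 bins of genes by GC content in percent (x axis) and on the right by gene type and exon overlap on the opposite strand (bars), for genes of at least 10 CPM. Replicate 2 minus 1 goes from 0.32 in the bin of lowest GC content to -1.37 in the highest, and the 126 antisense genes with overlap lie at 3.13 for replicate 2 minus 1 and 3.72 for replicate 3 minus 1.

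BET genes encode the proteins that MZ1 binds. BRD2 (ENSG00000204256.11, chromosome 6, 32968660 to 32981505, plus strand) had 127 ± 12.7 CPM. BRD3 (ENSG00000169925.15, chromosome 9, 134030305 to 134068535, minus strand) had 5.86 ± 1.88 CPM, from 31, 12 and 5 counts. By the chi-square test neither BRD2 (adjusted p = 0.0700) nor BRD3 (0.489) passed the threshold for variation between libraries. BRD2 and BRD3 have exons that overlap genes on the opposite strand.

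All 8 listed genes of the VHL ubiquitin ligase and its modifiers, the machinery that MZ1 recruits, reached 1 CPM in every library. VHL, the substrate receptor (ENSG00000134086.7, chromosome 3, 10141008 to 10152220, plus strand), had 78.2 ± 12.6 CPM. The scaffold gene CUL2 had 31.9 ± 7.0, the elongin gene ELOC 88.2 ± 10, the ubiquitin-conjugating enzyme gene UBE2R2 38.7 ± 5.17 and NEDD8, which encodes the modifier of cullins, 68.5 ± 17.7 CPM. Differences between libraries were larger for ELOB, at 106, 3.14 and 25.3 CPM in replicates 1, 2 and 3, UBE2M at 198, 39.6 and 173 and RBX1 at 171, 55.9 and 86.7 CPM. ELOB exons overlap SRRM2, and NEDD8 exons GMPR2, on the opposite strand. In this list 5 of 8 genes varied between libraries by the chi-square test over all genes, and 5 adjusted over the list alone.

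CRBN, the receptor of the other ligase widely used by degraders, had 25.2 ± 4.83 CPM, and its partners DDB1, CUL4A and CUL4B had 426 ± 103, 87.1 ± 19.5 and 78.4 ± 6.55 CPM. CRBN, DDB1 and CUL4A have exons that overlap genes on the opposite strand. VHL lay above CRBN in 3 of 3 libraries, with a log2 ratio of 1.62 ± 0.09 (exact two-sided sign-flip permutation p = 0.25, the smallest 3 libraries allow, and 0.28 after adjustment over 10 pairs). Per kb of exon the ratio was 2.39 ± 0.08.

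**Figure D2:**
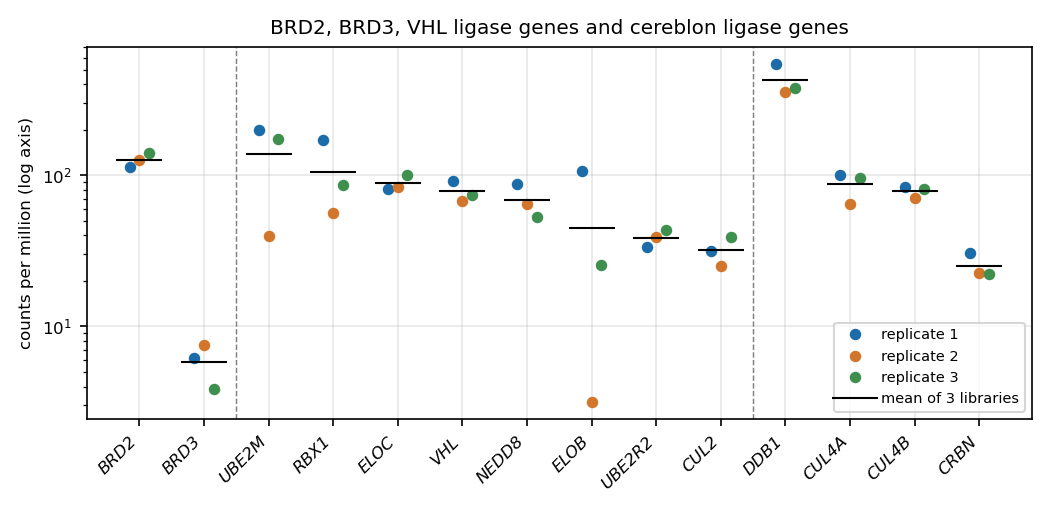
Expression in CPM (y axis, log scale) of BRD2 and BRD3, the VHL ligase genes and the cereblon ligase genes (x axis, separated by dashed lines), with 1 point per library and a bar at the mean. BRD2 has a mean of 127 CPM and BRD3 of 5.86 CPM, and ELOB spans 3.14 to 106 CPM.

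Genes of transcription elongation reached 1 CPM in every library in 13 of 13 cases, with list medians of 47.0, 48.4 and 67.5 CPM in replicates 1, 2 and 3. POLR2A, the largest RNA polymerase II subunit, had 479 ± 114 CPM, the elongation factor SUPT5H 375 ± 84.2 and CCNT1, the cyclin of P-TEFb, 277 ± 28.4 CPM. HEXIM1, an inhibitor of P-TEFb, was the lowest of the list at 17.9 ± 10.6 CPM. It had 6.20, 20.7 and 26.8 CPM in the 3 libraries, from 31, 33 and 35 counts (chi-square test, adjusted p = 5.00e-10), and its exons overlap an opposite-strand gene. HEXIM1 lay below CDK9, the P-TEFb kinase at 83.6 ± 33.2 CPM, with a log2 ratio of -2.35 ± 1.60 and -1.43 without replicate 1 (exact permutation p = 0.25 over the 3 libraries).

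Genes often studied as responders to BET inhibition covered a wide range. BCL2, which blocks apoptosis, had 499.9 ± 222 CPM, the kinase gene CDK6 166 ± 69.9 and the kinase gene PIM1 142 ± 26.1 CPM. IL7R had no count, which allows up to 0.60, 1.89 and 2.30 CPM in replicates 1, 2 and 3. Of the 15 listed genes in the table, 13 had a mean of at least 1 CPM, and the list median lay at percentile 78.7 ± 11.7 of random lists of expressed genes. MYC had 30.7 ± 4.81 CPM, with no difference between libraries detected at this depth (chi-square test, adjusted p = 0.397). It lay above its partner MAX, at 40.9 ± 21.9 CPM, in 2 of 3 libraries, with a log2 ratio of -0.30 ± 0.93 (exact permutation p = 1), and per kb of exon the ratio was 0.24 ± 0.89. Listed targets of MYC had medians of 194, 254 and 246 CPM. NCL and NPM1, nucleolar proteins of ribosome assembly, had 3883 ± 2057 and 3433 ± 562 CPM, the lactate dehydrogenase gene LDHA 1118 ± 164 and PPAN, the lowest, 4.56 ± 1.79 CPM. In this list 13 of 20 genes were lowest in replicate 1, against 34% of all genes of at least 10 CPM. CDK6 and MAX have exons that overlap genes on the opposite strand.

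Genes typical of the ABC subtype lay above those of the germinal centre B cell-like (GCB) subtype. No other line was compared, so this sets different genes against each other within 1 line and does not test its subtype. The 23 ABC genes in the table reached 1 CPM in every library, with medians of 191, 234 and 244 CPM, and the 20 GCB genes had medians of 5.02, 4.70 and 9.58 CPM. The difference of the medians was 5.07 ± 0.45 on the log2 scale, a 33.6-fold difference in the same direction in 3 of 3 libraries (exact two-sided permutation p = 0.25). CFLAR, an inhibitor of death receptor signalling, had 1181 ± 129.5 CPM, STAT3 865 ± 276 and the cyclin gene CCND2 561 ± 74.8 CPM, while IL10 was the lowest ABC gene at 23.6 ± 4.89 CPM. Among GCB genes LRMP had 164 ± 63.3 and SMIM14 38.1 ± 4.94 CPM, and SERPINA9 had 0, 1 and 0 counts. IRF4, a transcription factor of activated B cells, had 401 ± 126 CPM and lay above BCL6, the germinal centre repressor at 18.7 ± 5.64 CPM, by a log2 ratio of 4.38 ± 0.71. CCND2 lay above CCND3, at 8.92 ± 6.09 CPM, by 6.24 ± 1.58, and by 5.33 without replicate 2, where CCND3 had 3 counts (exact permutation p = 0.25 for both pairs). CFLAR, CCND2, LRMP, SERPINA9, BCL6 and CCND3 have exons that overlap genes on the opposite strand.

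B cell identity genes had medians of 93.9, 56.1 and 98.9 CPM, and 18 of 20 had a mean of at least 1 CPM. CD74, the invariant chain of antigen presentation, had 2447 ± 1839 CPM, from 4439, 815 and 2085 CPM in replicates 1, 2 and 3. The transcription factor genes POU2F2 and SPIB had 2199 ± 997 and 1401 ± 219 CPM, while VPREB3 had 2, 0 and 0 counts. In this list 17 of 17 tested genes varied between libraries, and 17 adjusted over the list alone. B cell receptor signalling genes had medians of 183, 156 and 153 CPM. CD79A, a chain of the receptor complex, had 564 ± 296 CPM, the phospholipase gene PLCG2 418 ± 51.8 and the adaptor gene BLNK 352 ± 136 CPM, and the paracaspase gene MALT1 was the lowest at 20.3 ± 3.89 CPM. Plasma cell genes had medians of 21.1, 10.1 and 26.1 CPM. SEC11C had 227 ± 55.7, PRDM1, a regulator of plasma cell differentiation, 67.0 ± 10.1 and SSR4 48.8 ± 30.3 CPM, and TNFRSF17 had 2, 0 and 0 counts. BLNK, MALT1 and SSR4 have exons that overlap genes on the opposite strand.

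NF-kB target genes had medians of 109, 49.6 and 53.7 CPM, and 20 of 20 had a mean of at least 1 CPM. After CFLAR the highest were CD83 at 778 ± 186 and NFKBIA, the NF-kB inhibitor, at 701 ± 297 CPM, and the lowest was IER3 at 2.78 ± 2.42 CPM. NFKBIA lay above TNFAIP3, another feedback inhibitor at 87.1 ± 51.1 CPM, by a log2 ratio of 3.05 ± 1.5 (exact permutation p = 0.25), and by 3.89 without replicate 1. NFKBIA was lowest in replicate 1, with 372, 781 and 951 CPM in the 3 libraries, and TNFAIP3 highest, with 146, 63.5 and 52.2 CPM. In this list 13 of 20 genes were highest in replicate 1, against 43.1% of all genes of at least 10 CPM. Genes of the toll-like receptor and MYD88 list had medians of 19, 18.9 and 22.2 CPM, with UBE2N at 224 ± 43.2, IRAK1 at 61.0 ± 29.9, the adaptor MYD88 at 37.4 ± 14.1 and TLR7 at 0.543 ± 0.505 CPM. The JAK-STAT list had medians of 26.4, 20.1 and 21.5 CPM, led by STAT3, JAK1 at 400.0 ± 81.2 CPM and PIM1, and IL6 had no count. Interferon-stimulated genes had medians of 3.89, 8.08 and 12.6 CPM. OAS1 and MX1 had 206 ± 55.9 and 183 ± 103 CPM, RSAD2 had 0, 1 and 0 counts, and 13 of 13 tested genes varied between libraries (13 adjusted over the list alone). CFLAR, TNFAIP3, IER3, UBE2N, JAK1, IL6, OAS1, MX1 and RSAD2 have exons that overlap genes on the opposite strand.

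In the BCL2 family list, with medians of 62.7, 31.7 and 46.4 CPM, the highest genes were BCL2, the anti-apoptotic gene MCL1 at 293 ± 20.8 CPM and the pro-apoptotic gene PMAIP1 at 282 ± 13.5 CPM, and HRK was the lowest at 0.977 ± 1.19 CPM. BCL2 lay above MCL1 in 3 of 3 libraries by a log2 ratio of 0.69 ± 0.66, but per kb of exon the ratio was -0.73 ± 0.66. BCL2 lay above BCL2L1, at 54.1 ± 15.3 CPM, by 3.15 ± 1.05 and by 2.55 without replicate 2 (exact permutation p = 0.25 for both pairs). Targets of p53 had medians of 14.0, 28.9 and 39.1 CPM. MDM2, the ubiquitin ligase of p53, had 550.6, 1447 and 736 CPM in replicates 1, 2 and 3, BTG2 had 636 ± 85.9 and the CDK inhibitor gene CDKN1A 193 ± 97.0 CPM, and PHLDA3 was the lowest at 0.589 ± 0.523 CPM. MDM2, CDKN1A and BCL2L1 have exons that overlap genes on the opposite strand.

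Proliferation genes were expressed in all 3 libraries. S phase genes had medians of 82.0, 93.7 and 75.3 CPM, with the replication genes MCM7 at 522 ± 43.3, MCM5 at 447 ± 148 and PCNA at 237 ± 109.6 CPM and the cyclin gene CCNE2 at 4.23 ± 3.05 CPM. Genes of the G2 and M phases had medians of 86.4, 43.6 and 53.3 CPM, with TOP2A at 402 ± 94.7, MKI67 at 236 ± 77.4, NUSAP1 at 147 ± 26.0 and the mitotic kinase gene AURKA at 9.84 ± 5.59 CPM. The chi-square test called 20 of 20 of these genes as varying between libraries, and 20 adjusted over the list alone. Of the 20 genes, 18 were highest in replicate 1, against 43.1% of all genes of at least 10 CPM. The list of G1 cyclins and CDK inhibitors had medians of 37.4, 16.8 and 31.2 CPM, with CCND2, RB1 at 488 ± 113 CPM and CDKN1A the highest. The CDK inhibitor gene CDKN2B had no count, and neither had its neighbour CDKN2A, which was singled out after its values were seen. MCM7, CCNE2, CCND2 and CDKN1A have exons that overlap genes on the opposite strand.

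Heat shock genes had medians of 167, 439 and 736 CPM in replicates 1, 2 and 3, and 9 of 10 tested genes varied (9 adjusted over the list alone). The median falls on DNAJA1 in replicate 1 and on HSPH1 in the others, and over the 11 members the median log2 difference of replicates 2 and 3 from replicate 1 was 0.58, with 3 members lower. These 3 were HSPD1, BAG3 and HSPB1, at -0.41, -1.11 and -3.30, and with DNAJA1 and HSPH1 they were chosen after their values were seen. The chaperone genes HSP90AB1, HSP90AA1 and HSPA8 had 6455 ± 1779, 3830.4 ± 1395 and 1618 ± 648 CPM, and HSPA1B, which has a near-identical copy, had 2.51 ± 2.10 CPM. Immediate early genes had medians of 54.6, 23.3 and 35.3 CPM, and 13 of 15 were highest in replicate 1, with 12 of 14 tested genes varying between libraries (12 adjusted over the list alone). The transcription factor gene EGR1 had 1007, 344 and 396 CPM, the phosphatase gene DUSP2 607, 54.1 and 155 and EGR2 119, 31.4 and 23.0 CPM, and DUSP1 had 13, 0 and 1 counts. Genes of the unfolded protein response had medians of 105, 56.1 and 45.9 CPM, and 8 of 12 tested genes varied (8 adjusted over the list alone), with HSP90B1 at 3647 ± 1088, ATF4 at 406 ± 95.3, HSPA5 at 399 ± 63.0 and CHAC1 at 1.16 ± 1.21 CPM. HSP90AA1, HSPD1 and HSP90B1 have exons that overlap genes on the opposite strand.

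Ribosomal protein and mitochondrially encoded genes had the highest list medians. The 25 ribosomal protein genes had medians of 2971, 803 and 1930.1 CPM, and 25 of 25 varied between libraries (25 adjusted over the list alone). RPS14 and RPS6, at 7832 ± 1606 CPM, were among the highest, and RPS27, the lowest, had 1093, 120.0 and 125 CPM. The 13 mitochondrial genes had medians of 8833, 5404 and 6399 CPM, the lowest being MT-ND4L at 1145 ± 346 CPM. Chromatin regulators mutated in lymphoma had medians of 109, 87.7 and 99.5 CPM. The methyltransferase gene EZH2 had 292 ± 164 CPM, KMT2D 154 ± 27.1 and the acetyltransferase gene EP300 131 ± 49.6 CPM, and the linker histone gene HIST1H1E had 1.56 ± 1.53 CPM. RPS6, KMT2D and EP300 have exons that overlap genes on the opposite strand.

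Of the markers of other cell types, 4 of 12 T and NK cell genes are in the table, and 2 had a mean of at least 1 CPM. TRAC had 7.44 ± 3.87 CPM, CD5, which some B cells also express, 17.4, 0.629 and 2.30 CPM in the 3 libraries, CD2 7, 0 and 0 counts and CD4 2, 1 and 0 counts. Of the myeloid markers 5 of 12 are in the table, with MPO at 24.7 ± 6.22, ITGAM at 19.4 ± 3.23 and LYZ at 5.44 ± 1.39 CPM and CD33 at 0, 1 and 0 counts. ITGA2B, an erythroid and platelet marker, had 4.35 ± 0.611 CPM. Of the stromal and epithelial markers 7 of 14 are in the table. VIM, which lymphoid cells also express and whose exons overlap an antisense gene, had 1591, 448 and 466 CPM, KRT8 32.4 ± 14.1 and PECAM1 7.99 ± 3.30 CPM, and PDGFRB had 4, 0 and 0 counts. LYZ and KRT8 have exons that overlap genes on the opposite strand.

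**Figure D3:**
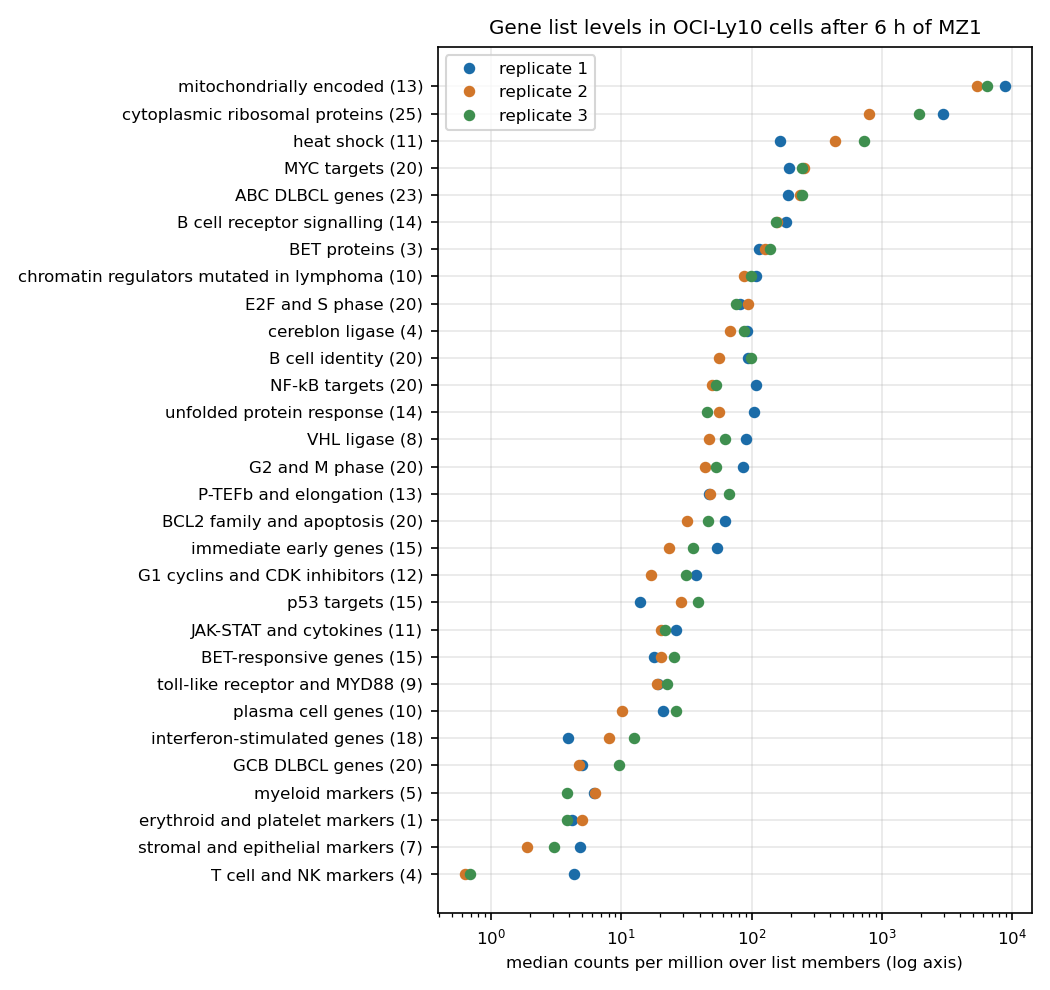
Median CPM over the members of each of 30 gene lists (x axis, log scale; lists on the y axis), with 1 point per library and the number of members in the table in brackets. The ABC list lies at 191, 234 and 244 CPM and the GCB list at 5.02, 4.70 and 9.58 CPM, and the heat shock list spreads from 167 to 736 CPM, where the median falls on another member in replicate 1.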

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

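The spread between libraries depended on the libraries used and on the filter for low counts, and little on opposite-strand exon overlap. No paired analysis was possible because the labels give 1 group. The number of genes varying between libraries, 6728 of 10016, ranged from 2854 to 5890 with 1 library left out. It was lowest without replicate 1, the deepest library. Among genes with no opposite-strand exon overlap, where fewer genes were tested, it was 3815 of 5736, nearly the same share. The coefficient of variation of 39.4% ranged from 30.1% to 47.8% with 1 library left out and was 52.8% with no filter on low counts (the cause was not tested). Among genes with no opposite-strand exon overlap the coefficient was 39.1%. The log2 ratio of BCL2 to MCL1 reversed to -0.73 per kb of exon, since the merged exons of BCL2 are longer, and 4 of the other pairs moved by more than 1 SD between libraries. That of MYC to MAX, whose sign differed between libraries, was -0.30 and turned to 0.24 per kb of exon and to 0.24 without replicate 3. The count of expressed genes, 10743, ran from 7311 with at least 10 counts in every library to 14095 with 1 CPM in any library. The ABC minus GCB difference ran from 4.63 per kb of exon to 5.31 without replicate 3, and 24 of 30 lists lay above the middle of the random lists under each alternative run. Of the percentiles of single lists, 43 moved by more than 1 SD between libraries and 317 did not, with 12 of the former per kb of exon, 13 with means and 11 with random lists from all genes. Of the levels of named genes, 85 moved and 743 did not, and 82 of the former were under the deposited log2 values, whose library constants are smaller. Thinning, the overlap filter and the GC trend removal were chosen after seeing the data. Depth limits low genes, since 1 count is worth 0.20 CPM in replicate 1 and 0.767 CPM in replicate 3.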

Other observations

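The tests of GC content as the whole cause and of gene length were chosen after their results were seen; thinning, GC trend removal and the patterns themselves were chosen after seeing the data.

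Further genes, chosen after their values were seen, add to the description of the treated cells. They lie outside the lists except CCL3 and CCL4, which belong to the NF-kB targets and are already part of that list's values. Among immunoglobulin constant genes IGHM, the heavy chain of IgM, had 3719, 312 and 1609 CPM in replicates 1, 2 and 3, IGKC 321 ± 148 CPM (SD, n = 3) and IGHD 28.1 ± 4.98 CPM. The chemokine gene CCL22 was nearly even, at 386 ± 8.44 CPM, while the chemokine gene CCL3 had 315, 37.7 and 47.6 CPM and CCL4 had 112, 44.0 and 15.3 CPM. The adhesion receptor gene CD44 had 860.2 ± 141 CPM, the chemokine receptor gene CXCR4 178 ± 86.2 and CD69, an early activation marker, 126, 5.03 and 29.2 CPM. Of long non-coding RNAs, MALAT1 had 3161 ± 845, NEAT1 332 ± 126, NORAD 224 ± 67.0 and MIR155HG, the host gene of a B cell microRNA, 82.2 ± 22.6 CPM, and the p53-responsive PURPL had 23.6, 143 and 82.1 CPM. CCL3, CD44 and MALAT1 have exons that overlap genes on the opposite strand.

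Antisense genes of at least 10 CPM (137 genes) were higher in replicates 2 and 3 than in replicate 1. Relative to protein-coding genes their median log2 shift was 2.54 with the GC trend removed (95% bootstrap interval 1.96 to 4.55) and 2.58 with libraries thinned to equal depth (1.76 to 4.51), which argues against GC content and depth. The shift was larger by 2.45 (1.04 to 3.91) in the 126 antisense genes whose exons overlap opposite-strand exons than in the 11 without overlap, so a candidate explanation is that strand was treated differently between the libraries, although the labels name 1 kit for all of them. The bootstrap intervals here cover spread between genes, which are not independent replicates, and hold no spread between libraries. The cutoff of 10 CPM was set on the mean of the same 3 libraries. Genes low in replicate 1 could thus pass it through replicates 2 and 3, which can enlarge these shifts and their difference. With no cutoff, antisense genes took 0.251%, 2.04% and 2.09% of the counts in replicates 1, 2 and 3. DNA or unspliced RNA stays open, since antisense genes without overlap were also shifted, by 0.99 (0.67 to 1.41), and sense-intronic genes numbered 4. No biological explanation was tested, as the design gives 1 group.

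The 3 libraries differed gene by gene far beyond counting noise, with replicate 1 apart from the others. With replicate 1 thinned to the depth of replicate 3, 44.0% of 8179 tested genes still differed between them, against 33.8% between replicates 2 and 3. This argues against the power of a deeper replicate 1 as the whole cause of its distance from replicate 3. Replicate 2 was not compared in this way. The test scales for depth and called 0 of 10033 simulated unchanged genes, so calls were not expected from unequal depth alone. With the GC trend removed the median SD of log2 values went from 0.492 to 0.454. The latter is 3.64 times that of Poisson counts, which argues against the removed GC trend as the whole cause. Any other spread between samples would also raise this ratio, so it decides nothing on GC content as part of the cause. GC content as part of the cause stays open. Its rho across genes was -0.435 for replicate 2 minus 1, -0.139 for replicate 3 minus 1 and 0.466 for replicate 3 minus 2. Gene length also stays open, with rhos of 0.244, 0.0453 and -0.321 in the same order. Both trends were weakest between replicates 1 and 3, so they set replicate 2 apart more than replicate 1, while separate cultures and library batches were not tested, since the labels give neither, and no biological explanation was tested.

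The heat shock list had a higher median in replicates 2 and 3 than in replicate 1, and its members shifted by a median of 0.74 on the log2 scale relative to protein-coding genes. Its members went both ways, from DNAJA1 at 2.19 to HSPB1 at -3.30, before subtracting protein-coding genes. The list's shift was 0.72 with the GC trend removed (95% bootstrap interval -0.33 to 1.19) and 0.74 (-0.95 to 2.28) over the 7 members with no opposite-strand exon overlap. Both values are nearly the same as the 0.74 over all members. Both intervals cover spread between genes and not between libraries. Both include 0, so with so few members a shift of the list itself is not established. GC content and strand handling thus stay undecided, and no biological explanation was tested.

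With the GC trend removed, 19 of 20 genes of the G2 and M phases, 11 of 15 immediate early genes and 11 of 20 NF-kB targets were highest in replicate 1, against 43.4% of all genes of at least 10 CPM. Before it these were 18, 13 and 13 genes and 43.1%, and the counts were chosen after seeing the data. Of markers of other cell types, 7 of 7 stromal and epithelial, 3 of 4 T and NK cell and 3 of 5 myeloid genes were highest in replicate 1. With the GC trend removed these were 6, 3 and 2, and the 1 erythroid and platelet gene was not highest there in either case. Only 2 stromal and epithelial and 2 myeloid markers had a mean of at least 10 CPM, so the shares above are no background for them. At few counts, genes with no count in the shallower replicates 2 and 3 take this order, and no matched share was computed.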
